A study of Penaeus vannamei with 11 samples.

How the data were processed

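RNA was sequenced from hemocytes, the circulating blood cells, of male and female Pacific white shrimp (*Penaeus vannamei*), either controls or animals stimulated with the bacterium *Vibrio parahaemolyticus*. The labels give total RNA taken with Trizol and Illumina libraries. There were 11 libraries: 3 of control females, 2 of control males (numbered 2 and 3), 3 of Vibrio females and 3 of Vibrio males. A control male numbered 1 was not among the samples. The sources used here give neither the dose, route and time of the stimulation nor whether the replicates of a group were separate animals, pools of animals or repeats. The p values therefore measure spread between samples only.

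The deposited table gives a count and a deposited FPKM value (fragments per kilobase and sequencing depth) for each of 18803 genes in each library. The count columns hold whole numbers that sum to a different total in each library, so they were taken as raw counts. The ratio of count to FPKM, compared between libraries, had a spread of at most 1.53% of its median from the 1st to the 99th percentile over 9299 well-counted genes. The labels name cutadapt 1.9 and FastQC. Aligner, counting program, genome build and strand setting are not given in the sources used here. The table pairs each identifier with a name, and 12678 genes carry a descriptive one. Of the 18803 identifiers, 12909 were also in the RefSeq reference table; names were taken from the deposited table alone. Gene positions lie on unplaced scaffolds of an unnamed build and are not printed.

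Depth ran from 39733829 to 53837438 counts per library, and 13210 to 15138 genes had a count. Even numbers made up 61.3 to 68.2% of the counts between 1 and 20 in a library, so a count is not 1 independent fragment. A count of 0 was taken to allow up to 3 counts of a library's total. That limit assumes independent counts, so it may be too low, and it covers counting error only. Counts between libraries of a group differed by a chi-square per degree of freedom of 118 to 538, so no library duplicated another of its group.

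Genes were tested with edgeR 4.0.16 in R 4.3.3. Of the 18803 genes, 14295 passed filterByExpr and 4508 were left out. Counts were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 11 libraries with 4 group means, and 5 contrasts were tested, all two-sided. These were Vibrio against control in females, Vibrio against control in males, the difference between those effects, males against females in controls, and males against females with Vibrio. All 4 groups shared an estimate of the spread, because control males had 2 libraries. P values were adjusted by Benjamini-Hochberg over genes, and a gene was called at an adjusted p under 0.05. CPM are counts scaled to a common depth of 1e6 after TMM scaling. A standard error (SE) is the log2 fold change divided by the square root of its F statistic.

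Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Adjustment ran over the 24 lists with at least 5 tested members within each contrast. Camera compares the genes of a list with all other genes. The 25 lists, made from gene names, were antimicrobial peptides, lysozymes, prophenoloxidase and melanization, coagulation and transglutaminases, lectins, pattern recognition proteins, Toll and IMD pathway, JAK-STAT and antiviral signalling, cell adhesion and phagocytosis, lysosome and cathepsins, antioxidant enzymes, heat shock and chaperone proteins, apoptosis, cytoplasmic ribosomal proteins, mitochondrial respiratory chain, glycolysis and lactate, proteasome, DNA replication and cell cycle, histones, cytoskeleton, and markers of muscle, hepatopancreas, cuticle, gonad and nervous system. The contrasts, tests, lists, thresholds and the rule for named genes were chosen before the data were examined. The list memberships were then corrected by gene name, with 178 removed and 5 added. That was done after the gene-level calls had been seen and before any list was tested.

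The rule named called genes with a descriptive name whose groups did not overlap, with at least 5 FPKM in the higher group, and up to 3 called members of each list. It also allowed the most abundant member of each list, by mean FPKM, as a gene that did not pass. No gene was called by edgeR, so the rule left the most abundant members alone. Any other gene named was chosen after its values were seen: the 5 genes with a descriptive name and the smallest unadjusted p in each contrast, the genes past the threshold adjusted over the list alone, and genes called by an alternative. Genes whose name is shared by several genes are marked, since reads can be shared between copies.

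The fit was tested on simulated data with 50 genes of at least 5 CPM changed at each fold, genes being simulated independently of each other. In the female Vibrio contrast it recovered 22% of 2-fold, 82% of 4-fold, 94% of 8-fold and 100% of 16-fold changes, with 10 false calls among 13883 genes. In the contrast of the sexes with Vibrio it recovered 6, 86, 92 and 94% of the same folds, with 3 false calls among 13841 genes. All folds were changed at once in the same simulated data. In the real libraries genes moved together, which the simulation leaves out, so recovery there may be lower.

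The alternatives were DESeq2 1.42.0, upper-quartile factors, no filter, a mean FPKM of at least 5, limma on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 0.01), voom with quality weights, the replicate number as a block, only the libraries compared, a minimum absolute log2 fold change of 1, and each library left out in turn. For lists they were camera with an estimated correlation, and fry, whose p tests whether the genes of a list move on balance in a single direction. Chosen after the data had been seen were a covariate for hepatopancreas markers, leaving out the 3 libraries highest in those markers, the lists as they stood before correction, and the refits of genes past the threshold over the list alone without each library. The share of variance by group was tested with 100000 permutations of the library labels.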

Results

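The deposited data are RNA-seq counts of 18803 genes in hemocytes of male and female shrimp with and without Vibrio. The 10 most abundant genes took 8.6 to 11.8% of the counts of a library. Group values below are means ± SD over libraries, with n = 3 in each group except control males with n = 2.

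The most abundant transcripts were those of the cytoskeleton, of translation and of hemocyte immune proteins. Over all 11 libraries, actin clone 403 (LOC113813020) had 14734 ± 4600 CPM and elongation factor 1-alpha-like (LOC113820946) 14296 ± 1869 CPM. A putative antimicrobial peptide (LOC113801825) had 12144 ± 3129 CPM, a hemocyte transglutaminase-like gene (LOC113823934) 10872 ± 5868 CPM, penaeidin-3a-like (LOC113808997) 9416 ± 3334 CPM and an anti-lipopolysaccharide factor-like gene (LOC113800363) 8780 ± 3327 CPM. Crustacean hematopoietic factor-like protein (LOC113802754) had 5789 ± 2069 CPM. Antimicrobial peptides took 3.26 ± 0.42% of the counts in control females, 3.77% in control males, 3.43 ± 0.15% in Vibrio females and 4.55 ± 0.87% in Vibrio males. Transglutaminases and other coagulation genes took 2.55 ± 0.92, 1.06 ± 0.33, 1.50 ± 0.20 and 1.39 ± 0.44% in the same order.

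Libraries of a group lay apart from each other on the axes that carried most of the variance. The first principal component, with 38% of the variance, followed hepatopancreas markers, whose members had a median correlation of 0.83 with it, lectins (0.64) and pattern recognition proteins (0.60). The second, with 14.9%, followed the proteasome (0.86), the respiratory chain (0.79) and ribosomal proteins (0.68). The 4 groups together accounted for 24.6% of the variance, against a mean of 30% under random labels (permutation p = 0.782). Sex accounted for 7.7% (permutation p = 0.66) and Vibrio for 7.2% (permutation p = 0.744), against a mean of 10% for each.

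**Figure D1:**
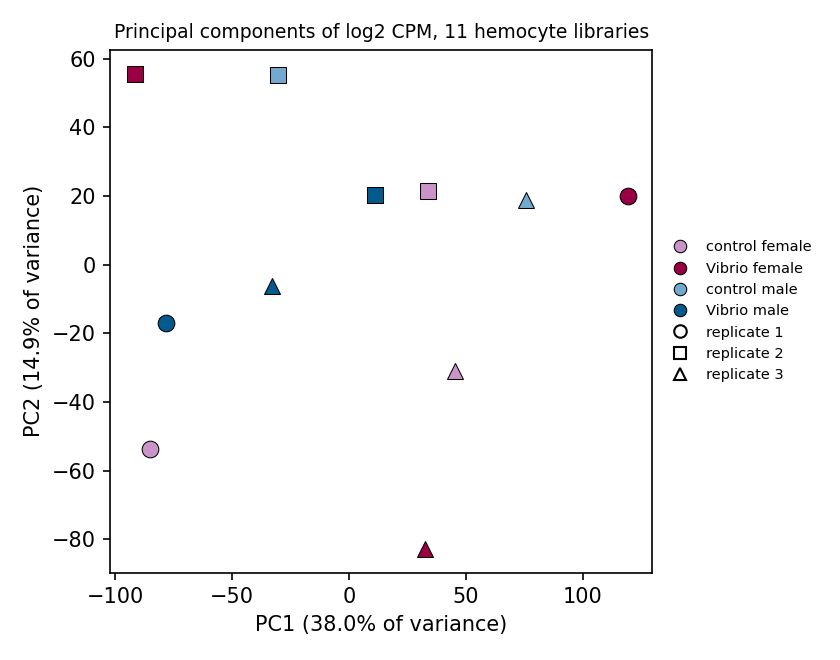
Scores of the 11 libraries on PC1 (38% of variance) and PC2 (14.9%) of log2 CPM, in arbitrary units, with color for group and shape for replicate number. Libraries of the same group are spread over the plot, with Vibrio female replicate 1 at 119.1 and Vibrio female replicate 2 at -91.4 on PC1.

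The comparison of Vibrio with control females asked how hemocytes of females differed after stimulation. Genes of protein turnover, translation and energy supply stood higher with Vibrio. Of the proteasome genes, 41 of 46 were higher (median log2 difference 0.40, camera adjusted p = 1.03e-07), as were 78 of 86 ribosomal protein genes (0.28, 1.14e-06), 65 of 69 respiratory chain genes (0.28, 9.82e-06) and 37 of 40 lysosome and cathepsin genes (0.38, 6.96e-05). Glycolysis (19 of 23, camera adjusted p = 0.00106), DNA replication (33 of 47, 0.00376), histones (13 of 14, 0.00758) and antioxidant enzymes (42 of 59, 0.00822) were also called higher. Muscle markers were called lower (27 of 41, median log2 difference -0.26, 0.00419). None of these 9 lists was called with an estimated correlation: adjusted p = 0.935 with an estimated correlation for glycolysis and 0.971 for the others. The calls leaned on single libraries. Without Vibrio female replicate 2, 2 lists were called and the adjusted p was 0.326 for the proteasome and histones, 0.366 for ribosomal proteins, 0.865 for the respiratory chain, 0.0941 for glycolysis, 0.394 for DNA replication, 0.459 for antioxidant enzymes and 0.522 for muscle markers. Without control female replicate 1, 3 lists were called, with 0.0522 for ribosomal proteins and for the lysosome. DNA replication and histones were also lost without control female replicate 3 or Vibrio female replicate 1, antioxidant enzymes without Vibrio female replicate 1 and muscle markers without control female replicate 3. Without the 3 libraries highest in hepatopancreas markers, 4 lists were called.

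No immune list was called in females. Antimicrobial peptides had 8 of 14 members higher, with a median log2 difference of 0.33, a mean of 0 and a test pointing down (camera adjusted p = 0.939, adjusted p = 0.993 with an estimated correlation). Lectins (median 0.43, mean -0.12, test down, 0.939), pattern recognition (0.09, -0.18, down, 0.774) and coagulation (-0.25, 0.31, down, 0.985) also differed in sign between measures, as did apoptosis (-0.12, 0.08, down, 0.838) and cytoskeleton (0.06, -0.09, up, 0.883). Prophenoloxidase and melanization genes were lower in 16 of 25 members (camera adjusted p = 0.44). The Toll and IMD pathway gave an adjusted p of 0.939, JAK-STAT and antiviral signalling 0.738, cell adhesion 0.939 and heat shock proteins 0.196. Markers of hepatopancreas gave 0.258, cuticle 0.939, gonad 0.939 and nervous system 0.569. Of 6 lysozyme genes 4 were tested, and lysozyme C-like (LOC113802295) had 1569 ± 666 CPM in control and 1020 ± 883 CPM in Vibrio females.

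At the level of single genes in females, edgeR called 0 of 14295 genes, with 579 at an unadjusted p under 0.05 where 715 would arise by chance and a smallest adjusted p of 0.986. DESeq2 called 21 genes, 10 higher and 11 lower. Adjusted over the list alone, edgeR passed 5 genes, against 0 over all genes. That adjustment ran within each of the 25 lists and 5 contrasts and not across them, so some passes would arise by chance. Pyruvate kinase-like (LOC113828822, a name shared by 2 genes) went from 316 ± 42 to 655 ± 213 CPM, a log2 fold change of 1.05 with SE 0.25 and an adjusted p over the list alone of 0.0349. V-type proton ATPase subunit B (LOC113821152), a lysosomal acidification gene, went from 49.6 ± 10.7 to 98.6 ± 17.3 CPM (0.0481). The anti-lipopolysaccharide factor-like gene LOC113800363 (a name shared by 8 genes) went from 5020 ± 1003 to 10500 ± 2900 CPM (0.0499), and the putative antimicrobial peptide LOC113801814 (2 genes of that name) from 4.20 ± 0.24 to 2.04 ± 0.48 CPM (0.0499). The putative hemocyte transglutaminase LOC113826241 went from 0.721 ± 0.41 to 14.1 ± 11.3 CPM (0.0394). For each of these 5 genes the adjusted p over the list alone was highest without control female replicate 1, from 0.147 for the transglutaminase to 0.208 for the ATPase subunit. Of the 11 fits that leave out a library, LOC113801814 passed in 0, LOC113800363 and LOC113821152 in 1, LOC113828822 in 3 and LOC113826241 in 4.

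Among the genes with the smallest unadjusted p in females, nicotinamide phosphoribosyltransferase-like (LOC113828203) went from 43.1 ± 8.0 to 91.7 ± 16.2 CPM, with a log2 fold change of 1.09 and SE 0.21. Cleavage stimulation factor subunit 3-like (LOC113825629, 2 genes of that name) went from 33.7 ± 0.66 to 19.3 ± 0.50 CPM (-0.80, SE 0.145). Inositol polyphosphate 5-phosphatase E-like (LOC113804514) went from 88.9 ± 10.1 to 45.4 ± 5.1 CPM (-0.97, SE 0.185). DESeq2 called these with adjusted p of 0.00171, 2.57e-06 and 0.00589; the edgeR adjusted p was 0.986 for each. DESeq2 also called nuclear hormone receptor FTZ-F1-like (LOC113828208), lower with a log2 fold change of -2.59 (adjusted p = 0.0324). These genes were chosen after their values were seen.

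**Figure D2:**
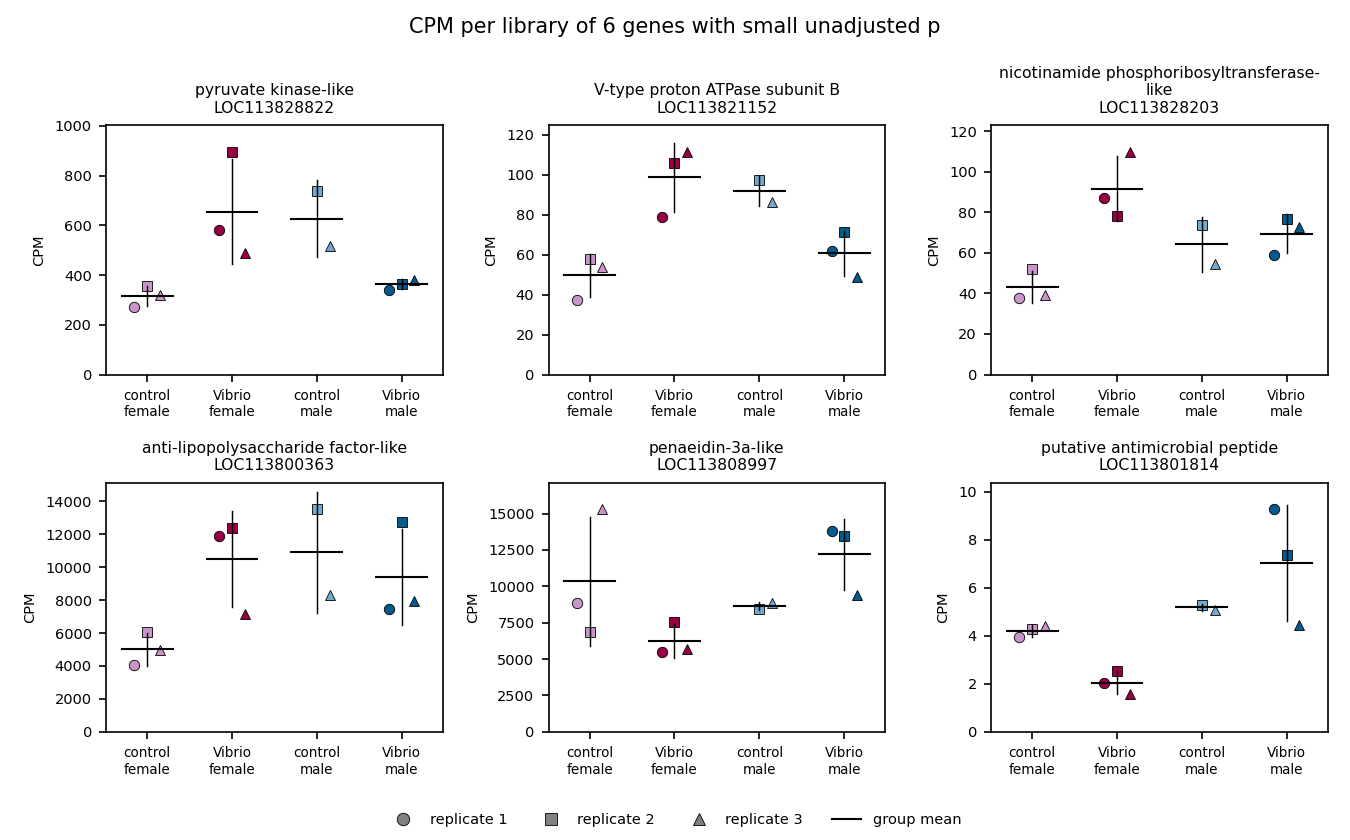
CPM per library (linear axis) of 6 genes with small unadjusted p, chosen after the values were seen; points are libraries (shape for replicate), horizontal lines group means and vertical lines ± SD. Pyruvate kinase-like and V-type proton ATPase subunit B are higher in Vibrio females than in control females (655 against 316 CPM and 98.6 against 49.6 CPM) and lower in Vibrio males than in control males (363 against 627 CPM and 60.7 against 91.8 CPM).

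The comparison of Vibrio with control males asked the same of males, with 3 libraries against 2. Ribosomal, respiratory chain, proteasome, lysosome and antioxidant genes, called higher with Vibrio in females, stood lower in males, while glycolysis (camera adjusted p = 0.277), DNA replication (0.49) and histones (0.496) were not called. Of the ribosomal protein genes, 78 of 86 were lower (median log2 difference -0.56, camera adjusted p = 2e-09), as were 62 of 69 respiratory chain genes (-0.53, 4.8e-09), 49 of 59 antioxidant genes (-0.48, 4.97e-06) and 42 of 46 proteasome genes (-0.41, 6.1e-05). Lysosome (31 of 40, camera adjusted p = 0.00283) and cytoskeleton genes (29 of 40, 0.00283) were also called lower. So were pattern recognition proteins (12 of 18, median -1.26, 0.0443), together with markers of hepatopancreas (80 lower and 20 higher, median -1.60, 0.0025) and of muscle (25 of 41, 0.0443). The share of counts in muscle markers ran the other way, from 0.526 ± 0.143% in control to 0.705 ± 0.041% in Vibrio males. None was called with an estimated correlation: adjusted p = 0.83 with an estimated correlation for all 9. Without control male replicate 2, 3 lists were called, the ribosomal list pointed up (0.166), the respiratory chain gave 0.166 and the proteasome 0.423, and antioxidant and cytoskeleton genes were lost. Without control male replicate 3, 4 lists were called, and hepatopancreas markers, muscle markers and pattern recognition each gave 0.91. The lysosome was lost without either control male and gave 0.129 without Vibrio male replicate 3, and cytoskeleton genes were lost without either control male. Some calls were also lost without Vibrio male replicate 1 (hepatopancreas markers), 2 (pattern recognition, muscle) or 3 (pattern recognition), or without Vibrio female replicate 3 (pattern recognition, muscle). Without the 3 libraries highest in hepatopancreas markers, 5 lists were called. The fits without control male replicate 2, without control male replicate 3 or without those 3 libraries leave a single control male. It is assumed to vary like the other groups.

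Immune effectors in males were not called as lists. Lectins were lower in 32 of 50 members (median log2 difference -1.09, camera adjusted p = 0.0617, adjusted p = 0.83 with an estimated correlation). Antimicrobial peptides were higher in 8 of 14 members (median 0.21, 0.70), prophenoloxidase and melanization genes in 13 of 25 (0.286) and coagulation genes in 10 of 16 (0.539). The other lists had camera adjusted p from 0.0577, for cuticle markers, to 0.891, for the Toll and IMD pathway. The Toll, JAK-STAT, cell adhesion and nervous system lists differed in sign between median, mean and test. In single genes edgeR called 0 of 14295, with 345 at an unadjusted p under 0.05, a smallest adjusted p of 0.933, and 0 adjusted over the list alone. DESeq2 called 11 genes, 10 of them at 0 in at least 2 libraries. The other was eukaryotic translation initiation factor 4 gamma 1-like (LOC113823483, 2 genes of that name), at 8.86 ± 2.49 CPM in control and 26.7 ± 7.6 CPM in Vibrio males, with a log2 fold change of 1.59, SE 0.35 and a DESeq2 adjusted p of 0.024. Ferritin subunit-like (LOC113830150) had 309 ± 106 CPM in control and 158 ± 39 CPM in Vibrio males (-0.97, SE 0.28, edgeR adjusted p = 0.933). Its log2 fold change was -0.57 without control male replicate 2 and -1.28 without control male replicate 3. Both were chosen after their values were seen.

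**Figure D3:**
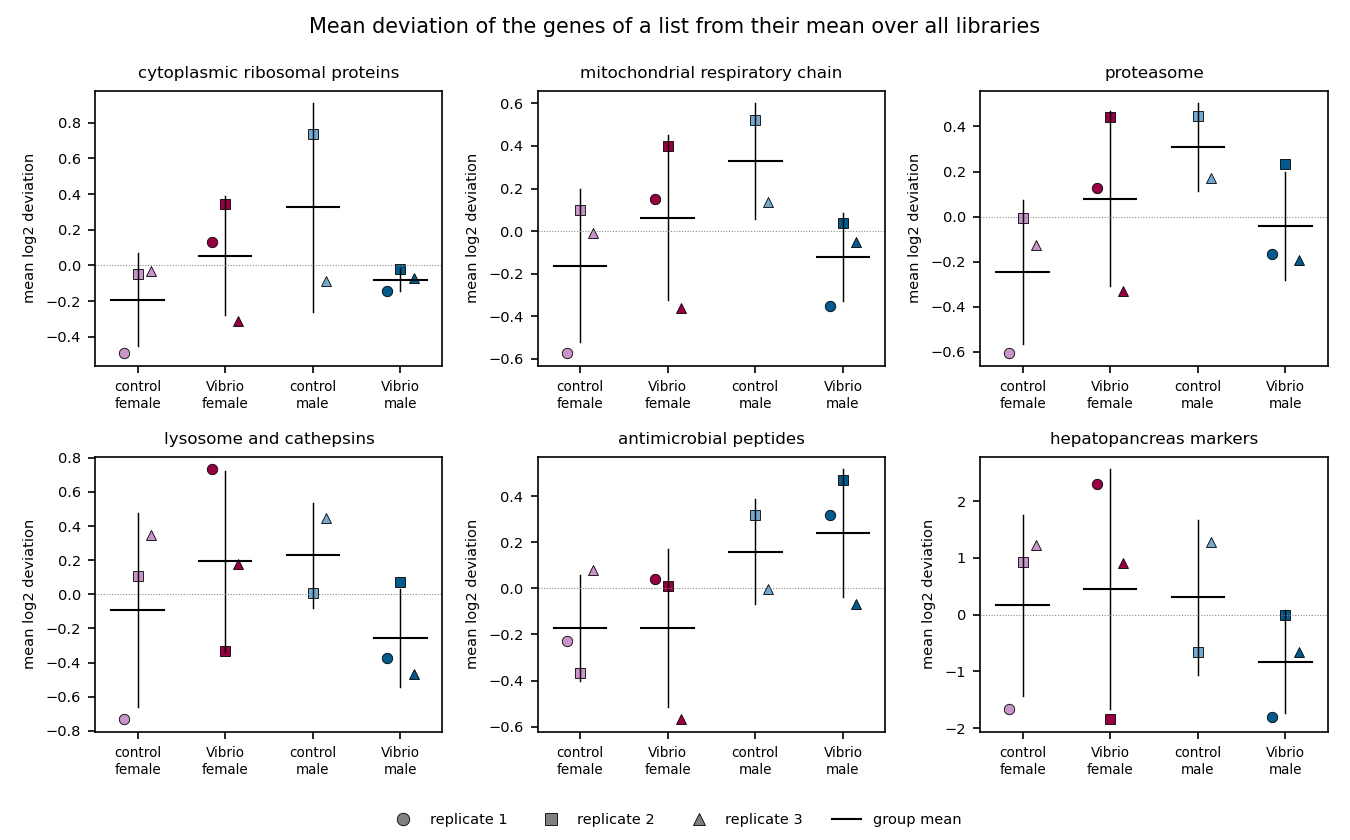
Mean log2 deviation of the genes of 6 lists from their mean over all 11 libraries, per library; points are libraries (shape for replicate), horizontal lines group means and vertical lines ± SD. Ribosomal proteins lie at 0.74 in control male replicate 2 and at -0.09 in control male replicate 3.

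Whether the response to Vibrio differed between the sexes, the question in the title of the series, was tested as the difference between the 2 effects. Genes of translation, respiration, proteasome and lysosome had the lower response in males. The list test called 11 lists, all lower in males: ribosomal proteins (82 of 86 members, median log2 difference -0.80, camera adjusted p = 3.35e-12), respiratory chain (65 of 69, -0.79, 3.81e-11), proteasome (42 of 46, -0.78, 2.35e-09), antioxidant enzymes (47 of 59, -0.70, 3.06e-06), lysosome (35 of 40, -0.74, 9.16e-06), hepatopancreas markers (0.00551), glycolysis (0.00668), DNA replication (0.0281), cytoskeleton (0.031), histones (0.0351) and heat shock proteins (0.0351). With an estimated correlation none was called: adjusted p = 0.705 with an estimated correlation for ribosomal proteins, respiratory chain, proteasome, antioxidant enzymes, lysosome, glycolysis and cytoskeleton, and 0.948 for the other 4. The refits that follow keep the preset correlation of 0.01, which treats genes that move together as nearly independent. They therefore do not test that setting. Respiratory chain, proteasome, antioxidant and lysosome genes stayed called without each of the 11 libraries in turn. The ribosomal list gave 0.0554 without control male replicate 2. Without control male replicate 3, glycolysis and histones gave 0.214, DNA replication 0.715 and hepatopancreas markers 0.455. Heat shock proteins gave 0.44 without Vibrio female replicate 2 and the cytoskeleton 0.184 without Vibrio female replicate 1. Heat shock, DNA replication, histones and cytoskeleton were each also lost without several other libraries, among them control female replicate 1 (heat shock, DNA replication, histones) and control female replicate 2 (cytoskeleton). The number of lists called was 5 without control male replicate 3, 7 without control female replicate 1 and 7 without Vibrio female replicate 1. It was 6 with hepatopancreas markers as a covariate and 5 without the 3 libraries highest in them.

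Pyruvate kinase-like (LOC113828822, 2 genes of that name) had the smallest p of the difference between the sexes. It was chosen for that p, so refits on parts of the same libraries give no independent support. It stood at 316 ± 42 and 655 ± 213 CPM in control and Vibrio females, and at 627 ± 155 and 363 ± 20 CPM in control and Vibrio males. The log2 difference of the effects was -1.84 with SE 0.36, and the adjusted p over the list alone was 0.0103. It stayed between 0.00422 and 0.0375 without each of the 11 libraries in turn, while the edgeR adjusted p over all genes was 0.74. V-type proton ATPase subunit B (LOC113821152, -1.59, SE 0.33) and its like-named gene LOC113822054 (-1.39, SE 0.32) both passed adjusted over the list alone at 0.0251. Each passed in 7 of the 11 fits that leave out a library, with the highest values of 0.0716 and 0.083 without control male replicate 2. Peritrophin-1-like (LOC113811921, 5 genes of that name), at 0 counts in 7 of 11 libraries, passed at 0.0471 but in 1 of those 11 fits alone, with the highest value of 0.231 without control male replicate 3. These 4 genes compare with 0 over all genes by edgeR, where 800 had an unadjusted p under 0.05 and the smallest adjusted p was 0.74. The adjustment over the list alone was not corrected across lists or contrasts. DESeq2 called 28 genes, 11 higher and 17 lower, among them pyruvate kinase-like (adjusted p = 0.00291), both ATPase genes (0.00655 and 0.022) and peroxiredoxin-6-like (LOC113823673, 0.0421). Of the 28, 13 were at 0 in at least 2 libraries.

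No immune list was called for a difference in response between the sexes. Camera adjusted p was 0.932 for antimicrobial peptides (median log2 difference -0.15, mean 0.08, test up), 0.174 for prophenoloxidase and melanization, 0.845 for coagulation (0.42, -0.31, up), 0.211 for lectins and 0.347 for pattern recognition. The other lists not called ran from 0.165, for cuticle markers, to 0.974, for the Toll, JAK-STAT, cell adhesion and muscle lists, the last 3 of which also differed in sign between measures. Across 8169 genes of at least 5 CPM, the log2 fold changes of females and males had a correlation of -0.20; genes are not independent replicates.

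Control males against control females asked for sex differences without Vibrio. Several groups of housekeeping genes stood higher in males. The 2 control male libraries also enter the male Vibrio contrast and the difference of effects with the opposite sign, so lists opposed between these contrasts are not independent findings. Called higher were ribosomal proteins (83 of 86 members, median log2 difference 0.61, camera adjusted p = 1.92e-13), proteasome (43 of 46, 0.67, 8.55e-13), respiratory chain (63 of 69, 0.58, 2.7e-12), antioxidant enzymes (46 of 59, 0.53, 1.23e-06), DNA replication (0.000171), lysosome (0.000233), heat shock proteins (0.00337), glycolysis (0.00766) and histones (0.0183). Antimicrobial peptides were also higher (9 of 14, 0.34, camera adjusted p = 0.0183). Coagulation genes (13 of 16 lower, -0.92, 0.0175) and prophenoloxidase and melanization genes (21 of 25 lower, -0.43, 0.0175) were lower in males. None of these 12 lists was called with an estimated correlation: the lowest was adjusted p = 0.569 with an estimated correlation, shared by ribosomal proteins, proteasome, respiratory chain and antimicrobial peptides among others. Ribosomal proteins gave 0.861 and antimicrobial peptides 0.515 without control male replicate 2. Antimicrobial peptides gave 0.261 without control female replicate 2. Coagulation gave 0.42 without control male replicate 3 and 0.288 without control female replicate 3, and prophenoloxidase gave 0.168 without control male replicate 2. Without control male replicate 3, DNA replication gave 0.2185, glycolysis 0.24 and histones 0.195. Some calls were also lost without control female replicate 1 (prophenoloxidase, histones), 2 (glycolysis) or 3 (prophenoloxidase, histones), or without Vibrio female replicate 3 (coagulation, prophenoloxidase). Without the 3 libraries highest in hepatopancreas markers, 6 lists were called.

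Among immune genes of controls, the hemocyte transglutaminase-like gene LOC113823945 (4 genes of that name) had 4044 ± 1674 CPM in females and 1778 ± 983 CPM in males (log2 fold change -1.19, SE 0.51, edgeR adjusted p = 0.756). Prophenoloxidase-1 (LOC113827090) had 3006 ± 1322 CPM in females and 1795 ± 127 CPM in males (-0.74, SE 0.44, 0.756). Peroxiredoxin-6-like (LOC113823673, 2 genes of that name), chosen after its values were seen, had 120 ± 18 CPM in females and 225 ± 46 CPM in males (0.91, SE 0.21) and was called by DESeq2 (adjusted p = 0.0427). Eukaryotic translation initiation factor 4 gamma 1-like (LOC113823483), chosen in the same way, had 42.3 ± 13.3 CPM in females and 8.86 ± 2.49 CPM in males (-2.26, SE 0.36), the smallest unadjusted p of the contrast. Sex-lethal (LOC113803286, 3 genes of that name), the most abundant gene among the gonad and sex-linked candidates, had 366 ± 19 CPM in control females and 376 ± 28 CPM in control males. edgeR called 0 of 14295 genes, with 698 at an unadjusted p under 0.05, a smallest adjusted p of 0.756, and 0 adjusted over the list alone; DESeq2 called 10. The 12 lists not called had camera adjusted p from 0.0528, for muscle markers, to 0.958, for JAK-STAT. Pattern recognition, JAK-STAT, apoptosis, hepatopancreas, cuticle and gonad lists differed in sign between median, mean and test.

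Vibrio males against Vibrio females asked for sex differences after stimulation. Antimicrobial peptides were higher in males, and lectins and pattern recognition proteins lower, the latter beside markers of hepatopancreas. Of the antimicrobial peptides, 11 of 14 were higher (median log2 difference 0.38, camera adjusted p = 0.00113, adjusted p = 0.856 with an estimated correlation). Lectins were lower in 45 of 50 members (-2.02, 0.00113) and pattern recognition proteins in 17 of 18 (-1.37, 0.0147), while 86 hepatopancreas markers were lower and 16 higher (-2.61, 7.7e-06). Also called lower were lysosome (37 of 40, camera adjusted p = 0.00496), cytoskeleton (34 of 40, 0.00935), ribosomal proteins (74 of 86, 0.00935), respiratory chain (60 of 69, 0.0155), coagulation (13 of 16, 0.0179), muscle (30 of 41, 0.0218) and cuticle (22 of 29, 0.0316). The share of counts in muscle markers was nonetheless higher in Vibrio males (0.705 ± 0.041%) than in Vibrio females (0.594 ± 0.123%). For these lists the adjusted p was 0.856 or 0.928 with an estimated correlation. Without Vibrio female replicate 1, the library highest in hepatopancreas markers, a single list was called: antimicrobial peptides (0.00503), with lectins at 0.725 and hepatopancreas markers at 0.373. Without Vibrio female replicate 3, antimicrobial peptides gave 0.121 and muscle markers 0.503. Ribosomal proteins gave 0.746 without Vibrio female replicate 2, the respiratory chain 0.425 without Vibrio male replicate 1, coagulation 0.29 without Vibrio male replicate 2 and the lysosome 0.3125 without Vibrio male replicate 3. The 11 calls fell to 6 with the uncorrected lists, to 3 with hepatopancreas markers as a covariate and to 2 without the 3 libraries highest in them.

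Adjusted over the list alone, 3 antimicrobial peptide genes passed in the comparison of the sexes with Vibrio, against 0 over all genes. That adjustment was not corrected across lists or contrasts. The genes were chosen for passing, so refits on parts of the same libraries give no independent support. The putative antimicrobial peptide LOC113801814 (2 genes of that name) had 2.04 ± 0.48 CPM in Vibrio females and 7.03 ± 2.42 CPM in Vibrio males, a log2 fold change of 1.78 with SE 0.32. Its adjusted p over the list alone was 0.00281 and stayed between 0.00106 and 0.0193 without each of the 11 libraries in turn. Penaeidin-3a-like (LOC113808997) had 6233 ± 1153 and 12200 ± 2455 CPM (0.97, SE 0.31), and crustin-like protein (LOC113816267) 1409 ± 180 and 2532 ± 358 CPM (0.85, SE 0.26). Both passed at 0.0459, but penaeidin-3a-like passed in 3 and crustin-like in 4 of the 11 fits that leave out a library, with the highest value of 0.162 for both without Vibrio male replicate 1. In the controls penaeidin-3a-like had 10330 ± 4415 CPM in females and 8638 ± 288 CPM in males. The abundant lectin nattectin-like (LOC113811918) had 819 ± 577 CPM in Vibrio females and 418 ± 72 CPM in Vibrio males (-0.97, SE 0.50). edgeR called 0 of 14295 genes, with 486 at an unadjusted p under 0.05 and a smallest adjusted p of 1. DESeq2 called 13, among them LOC113801814 (adjusted p = 0.00176) and venom protease-like (LOC113821989, 12 genes of that name, log2 fold change -1.76, adjusted p = 0.00384). Of the 13, 7 were at 0 in at least 2 libraries. The 13 lists not called had camera adjusted p from 0.0761, for antioxidant enzymes, to 0.938, for heat shock proteins; JAK-STAT, heat shock and nervous system lists differed in sign between measures.

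**Figure D4:**
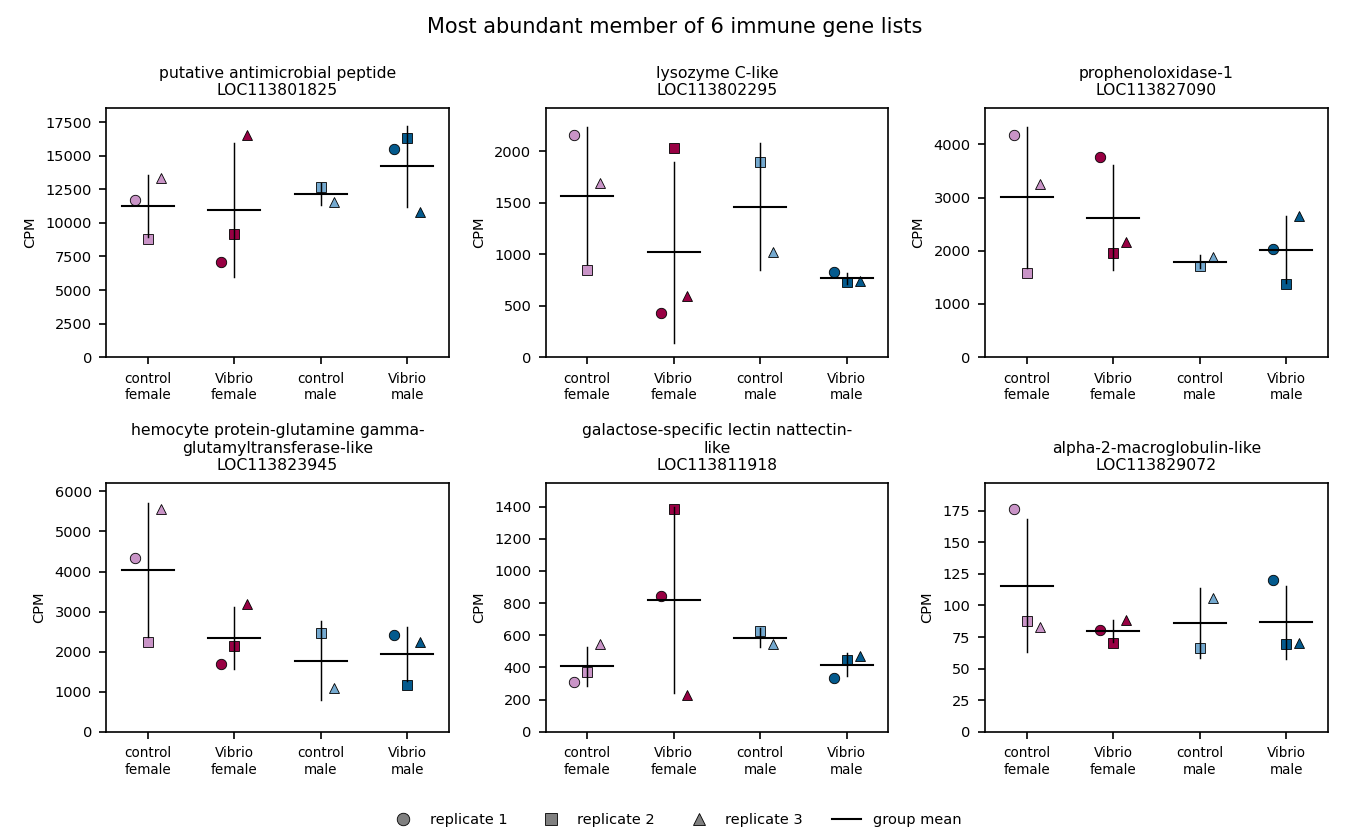
CPM per library (linear axis) of the most abundant member, by mean FPKM, of 6 immune gene lists. Points are libraries (shape for replicate), horizontal lines group means and vertical lines ± SD. None of the 6 was called by edgeR in any of the 5 comparisons.

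The other immune genes that led their lists in abundance had edgeR adjusted p of at least 0.74 in each of the 5 contrasts. The Toll ligand spaetzle (LOC113810575) had 304 ± 32 CPM in control females, 467 ± 288 CPM in control males, 287 ± 111 CPM in Vibrio females and 320 ± 72 CPM in Vibrio males. An integrin beta subunit (LOC113819144) had 2658 ± 584, 1992 ± 123, 2245 ± 169 and 2349 ± 675 CPM in the same order. Alpha-2-macroglobulin-like (LOC113829072, 2 genes of that name), a thioester protein, had 116 ± 52, 86.0 ± 27.9, 79.7 ± 9.0 and 86.8 ± 28.9 CPM. Hemocyanin (LOC113830072, 3 genes of that name), the most abundant hepatopancreas marker, ran from 4.03 to 515 CPM over the 11 libraries and moved with the hepatopancreas, lectin and pattern recognition lists on the first principal component.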

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

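The tests without control male replicate 2 and without control male replicate 3 were chosen only after the result was seen, and the covariate for hepatopancreas markers was added after the data had been seen.

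The difference between the male and the female response to Vibrio was tested for each gene list, and camera called 11 lists, all with a lower response in males. The mean log2 difference of the effects was -0.77 for lysosome and cathepsins (camera adjusted p = 9.16e-06), -0.71 for antioxidant enzymes (3.06e-06), -0.24 for heat shock and chaperone proteins (0.0351), -0.65 for ribosomal proteins (3.35e-12), -0.68 for the respiratory chain (3.81e-11) and -0.64 for glycolysis (0.00668). It was -0.67 for the proteasome (2.35e-09), -0.34 for DNA replication (0.0281), -0.60 for histones (0.0351), -0.47 for the cytoskeleton (0.031) and -1.43 for hepatopancreas markers (0.00551). For DNA replication the share of counts ran the other way, from 0.0570 ± 0.0083 to 0.0592 ± 0.0041% in females and from 0.0580 ± 0.0092 to 0.0634 ± 0.0035% in males. With an estimated correlation, adjusted p was 0.705 for lysosome, antioxidant enzymes, ribosomal proteins, respiratory chain, glycolysis, proteasome and cytoskeleton, and 0.948 for the other 4 lists.

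Several technical explanations were set against a biological difference between the sexes for these 11 lists. The tables argue against counting depth itself as the source. After all libraries were thinned to the smallest total, 10 of the 11 lists were still called. The median of the mean differences of the 11 lists was -0.68, against -0.65 before. Totals differed only 1.35-fold, and thinning leaves any other trait of a smaller library in place. Control male replicate 2, whose ribosomal proteins stood 0.74 above the mean on the log2 scale, stays open. Without that library 9 lists were still called (median -0.64), and the ribosomal and cytoskeleton lists were not. The median thus hardly moved, but the count cannot exclude a single library as the source. It rests on the preset correlation, and that fit leaves a single control male. Other splits of the libraries were not fitted for this contrast, so chance was not tested in that way. Camera with an estimated correlation (lowest adjusted p = 0.705) and fry (lowest adjusted p = 0.494) each called 0 lists. Chance can thus not be excluded. Control male replicate 3 stays open: without it 5 lists were still called (median -0.51). RNA of hepatopancreas in some libraries stays open too. With the covariate 6 lists were still called and the median moved to -0.38. The bound set before that result was at least 6 lists, which the value met with no margin, and the bound was tightened to more than 6 after the value was seen. The covariate is built from the hepatopancreas list, whose own loss was therefore fixed, so the 6 lists are to be read against the other 10. Of these, heat shock, DNA replication, histones and cytoskeleton were lost. The remaining lists may carry a sex difference in the response, as a hypothesis. A state of the cells that varied between libraries whatever their group is consistent with the loss of all calls under an estimated correlation (0 lists), and the members of the ribosomal, respiratory chain and proteasome lists moved together between libraries of the same group (estimated correlations of 0.58, 0.61 and 0.60). For cytoskeleton (0.066) and glycolysis (0.072) they hardly did.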

How the results depend on the processing

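The hepatopancreas covariate, leaving out the 3 libraries highest in hepatopancreas markers (Vibrio female replicate 1, control male replicate 3 and control female replicate 3), and the uncorrected lists were chosen only after the data were seen.

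The gene counts of edgeR were 0 in all 5 contrasts under the replicate block, upper-quartile factors, no filter, a mean FPKM of at least 5, limma on log2(FPKM + 0.1), voom with quality weights, only the libraries compared, a minimum fold and the covariate. The fit of only the libraries compared has no counterpart for the difference of effects. The replicate numbers did not pair the samples: 5 of 15 same-number pairs correlated above 0.1, with a median of 0.02 against 0.01 for other pairs. With the block, the genes at an unadjusted p under 0.05 were 609 for Vibrio against control in females, 282 for Vibrio against control in males, 765 for the difference of the Vibrio effect between males and females, 645 for males against females in controls and 397 for males against females with Vibrio. Other values keep that order. DESeq2 called 21, 11, 28, 10 and 13 genes, of which 3, 10, 13, 4 and 7 were at 0 in at least 2 libraries. The cause of the DESeq2 calls was not tested. Limma on log2(FPKM + 1) and on log2(FPKM + 0.01) each called 1 gene in males and 1 in controls by sex. With the 3 libraries left out, 2 genes were called in females. Leaving out each library in turn gave 0 to 1 genes in each contrast. These fits outside DESeq2 called 8 genes in all, each at 0 counts in 1 to 7 libraries, such as a zinc finger protein gene (LOC113814387). The most abundant members of the lists had 0 calls in every setting run.

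The list counts were 9, 9, 11, 12 and 11 as reported, 9, 9, 10, 11 and 10 with the block, and 0 in each contrast with an estimated correlation and with fry. The estimated correlations, 0.58 for ribosomal proteins and 0.60 for the proteasome, lie far above the preset 0.01. With the 3 libraries left out they were 4, 5, 5, 6 and 2. With the covariate they were 6 for the difference of effects and 3 for the sexes with Vibrio. The uncorrected lists gave 8, 6, 8, 12 and 6. Leaving out each library gave 2 to 11 lists in females (2 without Vibrio female replicate 2), 3 to 11 in males (3 without control male replicate 2), 5 to 12 for the difference (5 without control male replicate 3), 9 to 13 in controls and 1 to 12 with Vibrio (1 without Vibrio female replicate 1).

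Of the called lists, 607 values kept their side of the threshold, 268 lost the call in the same direction and 9 reversed; the cause was not tested. With the 3 libraries left out those reversed were the pattern recognition: beta-glucan binding, thioester and Dscam proteins list, Vibrio against control in males (0.988), the DNA replication and cell cycle list, difference of the Vibrio effect between males and females (0.863), and the cuticle and epidermis markers list, males against females with Vibrio (0.772). With the covariate it was the C-type lectins and other lectins list, males against females with Vibrio (0.942). Leaving out a library reversed pattern recognition in males (range 0.00418 to 0.91), ribosomal proteins in males (4.62e-27 to 0.166, 0.166 without control male replicate 2), and with Vibrio ribosomal proteins (1.01e-06 to 0.746, 0.746 without Vibrio female replicate 2), respiratory chain (1.12e-08 to 0.425, 0.179 without Vibrio female replicate 2) and cuticle (0.000258 to 0.833). None of the 33 fold changes of named genes run under the alternatives reversed; the folds of other named genes were not run there. DESeq2 scaling put the median of all genes at -0.135 for the difference and -0.124 for the sexes with Vibrio (TMM -0.076 and -0.092), and no called list changed the sign of its median under it, upper-quartile or FPKM scaling. At these depths the spread between libraries, not counting error, sets the limit: the common biological coefficient of variation was 0.58.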

Other observations

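The tests of splits for gene counts, all 3 tests on hepatopancreas markers, and for genes at 0 the tests of sex or treatment and of gene content were chosen only after the result was seen.

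Other splits of the same libraries were fitted for each comparison of at least 3 against 3. In females the real split gave 0 called genes, a count that all 10 of 10 splits reach by construction. The highest other split gave 267. It set control female replicates 1 and 3 and Vibrio female replicate 3 apart from the other 3 libraries, along the second principal component, which points to a structure of the samples beside the groups. For lists the real value was 9, reached by 5 of 10 splits, with 16 as the highest other. For the sexes with Vibrio the gene count was 0, again reached by 10 of 10 splits by construction, and the highest other was 0. The list count of 11 was reached by 4 of 10 splits, with 14 as the highest other. These 10 splits are too few for a share under 0.05.

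Pooling both sexes, with sex as a term, Vibrio against control (6 against 5 libraries) gave 0 genes by edgeR, with 258 at an unadjusted p under 0.05, and 1 list, muscle markers, lower with Vibrio (camera adjusted p = 0.00011, and adjusted p = 0.992 with an estimated correlation). The share of counts in these markers went from 0.685 ± 0.104 to 0.594 ± 0.123% in females but from 0.526 ± 0.143 to 0.705 ± 0.041% in males. As many lists came from 99 of 100 splits (highest other 14), so chance cannot be excluded for the list. The gene count of 0 is reached by all 100 splits by construction (highest other 51) and decides nothing. Pooling both treatments, males against females gave 0 genes, with 408 at an unadjusted p under 0.05, and 13 lists, 7 higher and 6 lower in males. As many lists came from 9 of 100 splits (highest other 15), so chance cannot be excluded for the lists. The gene count again decides nothing (100 of 100, highest other 79). Antimicrobial peptides were among the higher lists (2.99e-05, and adjusted p = 0.249 with an estimated correlation). With an estimated correlation 0 lists were called in both.

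Libraries differed in markers of the hepatopancreas, the digestive gland, across groups. The marker list was chosen before the data were examined, but 4 members were removed by name after the gene-level calls had been seen. The corrected list had only 23 genes with at least 1 CPM in every library, and 1 member was also in another list. Its share of counts was 0.142 ± 0.085% in control females, 0.215 ± 0.154% in control males, 0.194 ± 0.126% in Vibrio females and 0.0800 ± 0.0232% in Vibrio males, and hemocyanin ran from 4.03 to 515 CPM. Thinning cannot decide on library size here, since it keeps the expected share of a list in each library. The highest share after it, 6.06 times the lowest, was therefore fixed in advance. Totals differed 1.35-fold. The members moved together, with a median pair correlation of 0.46, above all 1000 random lists of like abundance (highest 0.11). A candidate explanation is RNA of hepatopancreas in some libraries; hemocytes that make these transcripts were not tested against it. A background that raises other low genes stays open. The score of a library is the mean log2 CPM of the markers. Genes outside all lists, matched on mean level, had a median slope of 0.03 on it (95% of 1000 random sets from 0 to 0.08). The slope of the markers themselves (median 1.15) averages 1 by construction, since they make up the score, and is no independent contrast. The mean levels of other tissue lists nonetheless followed the score, with correlations of 0.95 for gonad, 0.88 for cuticle, 0.71 for muscle and 0.63 for nervous system. The median correlation of their single members was lower, at 0.12, 0.60, 0.32 and 0.08 in the same order, so most gonad and nervous system genes did not follow it closely. The score also followed the number of genes with a count (Pearson r = 0.87, permutation p = 0.00053, adjusted 0.0011, Spearman rho = 0.95, permutation p = 2e-05, adjusted 4e-05, over 11 libraries). That r was 0.79 without the 2 libraries farthest from the median. It did not follow the total count (r = 0.21, permutation p = 0.6, adjusted 0.6, rho = -0.01, permutation p = 0.99, adjusted 0.99, r = 0.31 without the 2 farthest); 2 relations were computed.

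A set of 19 genes was at 0 in at least 3 libraries and at 2 CPM or more in at least 3 others. They were found in the data. Porwaprin-a-like (LOC113801831) was at 0 in control female replicates 1 and 2 and control male replicate 2, and at 32.8 to 195 CPM in the other 8 libraries. Mucin-12 (LOC113814449) was at 0 in 5 libraries and at 71.3 to 235 CPM in the others. A zinc finger protein gene (LOC113814387) was at 0 in all 3 Vibrio females and in control male replicate 3, and at 3.07 to 4.87 CPM elsewhere. A count of 0 was taken to allow up to 3 counts, or 0.0755 CPM in the smallest library, a limit that assumes independent counts. Of the 11 genes with a same-named partner, 0 had a partner whose level ran strongly opposite to theirs over the libraries. This argues against a full exchange of reads with a same-named copy for these 11 genes. An abundant partner that took in few of their reads would not be seen in this way. No such partner was found for the other 8 genes, which stay open. Partners were searched only for the 15 genes with a descriptive name, and only among genes that passed the filter. A response to Vibrio or a sex difference stays open: the 4 groups accounted for 39.8% of the patterns on average, against 30% under random labels (permutation p = 0.0208). For LOC113814387, DESeq2 gave an adjusted p of 3.61e-05 in females and 0.00181 for the difference of effects, where edgeR gave 0.986 and 0.74. Each of the 19 genes was on in some and off in other libraries of at least 1 group. No pattern thus followed the 4 groups in full. This does not exclude a response shared by all libraries of another group. LOC113814387 was mixed in control males alone, and porwaprin-a-like was on in every Vibrio library. All 19 genes had a pattern of libraries shared with no other, and 6 to 11 of them were at 0 in any library. Gene content that differs between animals is a possible explanation that cannot be told apart from silencing, since the source of the replicates is not given and no genome sequence of these animals was at hand.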
